A study of Homo sapiens with 8 samples.

How the data were processed

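Gene expression was measured in THP-1 cells, a human monocytic leukaemia line, by 2-colour Agilent arrays. Each of the 8 arrays carried RNA of cells treated with bacteria for 6 hours at a multiplicity of infection (MOI) of 1, labelled with Cy5, and RNA of time-matched untreated cells, labelled with Cy3. The dyes were not swapped on any array, so a gene-specific dye bias is part of every ratio against untreated cells. Lactobacillus acidophilus had 2 arrays, Bacillus clausii 3 and Bifidobacterium bifidum 3. The labels state 3 replicates per condition, and the third L. acidophilus replicate was not analysed here. The arrays lay on 2 slides of 4 arrays. Slide 1 held both L. acidophilus arrays, B. clausii replicate 1 and B. bifidum replicate 1, and slide 2 held replicates 2 and 3 of B. clausii and of B. bifidum.

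Per the file headers, the deposited scanner files hold, for each spot, the median brightness (intensity) of the spot and of its local background in both channels, without normalization. They also hold intensity values after Agilent's background subtraction and dye normalization, the log10 of Cy5 over Cy3 of those values (LogRatio), and other columns with quality flags per spot. The deposited value table holds log10 ratios. It was checked against the scanner files and is a rounded copy of their LogRatio, with correlations of 0.999999 to 0.9999995 per array and a median of 0 in every column. The file headers name Feature Extraction 10.7.3.1, while the authors' processing notes name version 10.5.1.1. The headers place the probes on hg19, an earlier build than the reference used for symbols, so no coordinates are given.

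Ratios were recomputed in R 4.3.3 with limma 3.58.1, and tables were read with the package data.table (version 1.17.8). Signals were background corrected by normexp with an offset of 50, and log2 ratios of Cy5 over Cy3 were normalized by loess within each array. The plan named the mean spot signal. The files hold no mean signal, so the median signal was used. Spots that the scanner software marked as outliers were left out, and the spots of a probe were averaged. Each array had 43376 spots of 41000 probes, besides 1639 control spots, and 86 probes were left out because all their spots were outliers on an array. A probe was kept when it was well above background in at least 1 channel on at least 2 arrays, which 32821 probes were. RefSeq accessions gave a symbol to 27210 probes (66.4%), and the other 13790 kept their accession from the files. The brightest probe stood for each gene, which left 25288 features, of which 16113 were named genes and 9175 were not matched to a symbol.

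The share of spots well above background was 55.2% to 69.6% in the Cy3 channel. In the Cy5 channel it was 75.2% to 77.9% on slide 1 and 41.6% to 60.5% on slide 2. Saturated Cy3 spots numbered 0 on each array of slide 1 and 42 to 88 on those of slide 2. Median signal over background was 2.33 to 4.04 per array and channel. The number of arrays limits the precision.

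Arrays were compared over 174 probes that are each spotted 10 times. For 3 pairs of arrays, both of 1 group and 1 slide, the squared difference between the arrays was 0.706 to 0.994 times the noise of the repeated spots. In the other 25 pairs it was 9.68 to 96.3 times that noise. The 3 pairs (L. acidophilus replicates 1 and 2, B. clausii replicates 2 and 3, B. bifidum replicates 2 and 3) differed by less than the noise, so each pair was averaged and counted as 1 sample. This left 5 samples: 1 of L. acidophilus, 2 of B. clausii and 2 of B. bifidum, with 1 sample of the latter groups on each slide. Counting these pairs once departs from the written plan, which used all 8 arrays, and was decided after the counts over 8 arrays had been seen. Those counts are given under "each array counted as a replicate".

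Each bacterium was compared with untreated cells (mean log2 ratio against 0), and the bacteria were compared with each other, in limma models (lmFit, eBayes) with 1 mean per group, at a Benjamini-Hochberg adjusted p under 0.05. This fit had 2 residual degrees of freedom (6.3 with limma's prior). The same comparisons were fitted with slide as an additive block, with 1 residual degree of freedom (13.3 with the prior). Against untreated cells, the block gives the mean over the slides, and its error leaves out the difference between the slides, which is the only replication of such a ratio. The standard errors given for these ratios are therefore those of the fit without a block. All standard errors given are limma's moderated errors, which pool the groups and draw on all features. They are not the spread between the samples of a group. The block's mean covers both slides, so the named genes are given with their value on each slide. Because L. acidophilus was on slide 1 alone, its blocked value rests on the slide difference seen in the other groups. L. acidophilus has 1 sample and is assumed to vary like the other groups.

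Before the data were examined, 43 gene lists, 15 single genes and the rule for named genes were fixed. The rule names the 8 genes with the largest rise and the 8 with the largest fall against untreated cells, and the 5 largest each way between bacteria. They must pass the adjusted p, have 1 sign on every array compared, and be well above background and unsaturated in both channels on those arrays. Up to 4 members of each list with the smallest adjusted p were added. CXCL8, among the 15 single genes, has no value because its probe did not pass the filter on dim probes. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives, adjusted over the lists of a comparison. The median of a list in each sample was ranked among 10000 random lists of like intensity (20 intensity bins). The fixed alternatives were an offset of 10, Agilent's LogRatio, the deposited value table, median centring without loess, scale and Aquantile normalization between arrays, no filter or a stricter filter on dim probes, the mean over probes, an intensity trend, a 2-fold limit, only the samples compared, slide or replicate blocks, split controls, and leaving out each array.

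Chosen after seeing the data were the counting of like arrays once, the replicate block with each array counted, the blocked counts as results of their own and the named-gene rule applied to them. So were the counts of genes past a log2 size of 0.3 or 0.5 on both slides, and the test of all 43 lists among the genes they gave. The models were tested on simulated data of 25288 genes, in which 50 genes were changed at each of 1.5-fold, 2-fold, 3-fold and 4-fold. Without a block, B. clausii against untreated recovered 0% of 1.5-fold, 44% of 2-fold, 90% of 3-fold and 98% of 4-fold changes, with 0 false calls. The contrast of B. clausii and B. bifidum recovered 0%, 0%, 50% and 78%. With slide as a block, B. clausii against untreated recovered 100% at each fold, with 21 false calls, and the contrast with B. bifidum recovered 82% at 1.5-fold and 100% above it, with 17 false calls. The simulated slide effects were equal and opposite, so they cancelled in the blocked mean, and the noise was that of the blocked fit. The recovery and the 21 false calls therefore do not measure the error of the blocked calls against untreated cells.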

Results

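The data were 8 2-colour arrays of THP-1 cells, a human monocytic leukaemia line, each comparing cells given bacteria for 6 hours with time-matched untreated cells. The bacteria were strains used as probiotics: Lactobacillus acidophilus (2 arrays, counted as 1 sample), Bacillus clausii (3 arrays, 2 samples) and Bifidobacterium bifidum (3 arrays, 2 samples). All values are log2 ratios of treated over untreated cells, or differences of these. The comparisons ask which genes each bacterium changed and whether the bacteria differed.

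Ratios followed the slide more than the bacterium. Across the 25288 features, which are not independent replicates, samples of different bacteria on the same slide correlated at 0.596 to 0.677. An untreated reference shared within a slide gave 0.499 to 0.5 in simulated data. That value follows from the equal noise given to treated and untreated RNA, without any response, so it is no test of a shared reference. Samples on different slides correlated at -0.0779 to 0.0194, including the samples of the same bacterium, at 0.0194 for B. clausii and -0.00456 for B. bifidum. For this reason values on slide 1 and slide 2, in this order, stand beside the blocked means of the named genes.

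**Figure D1:**
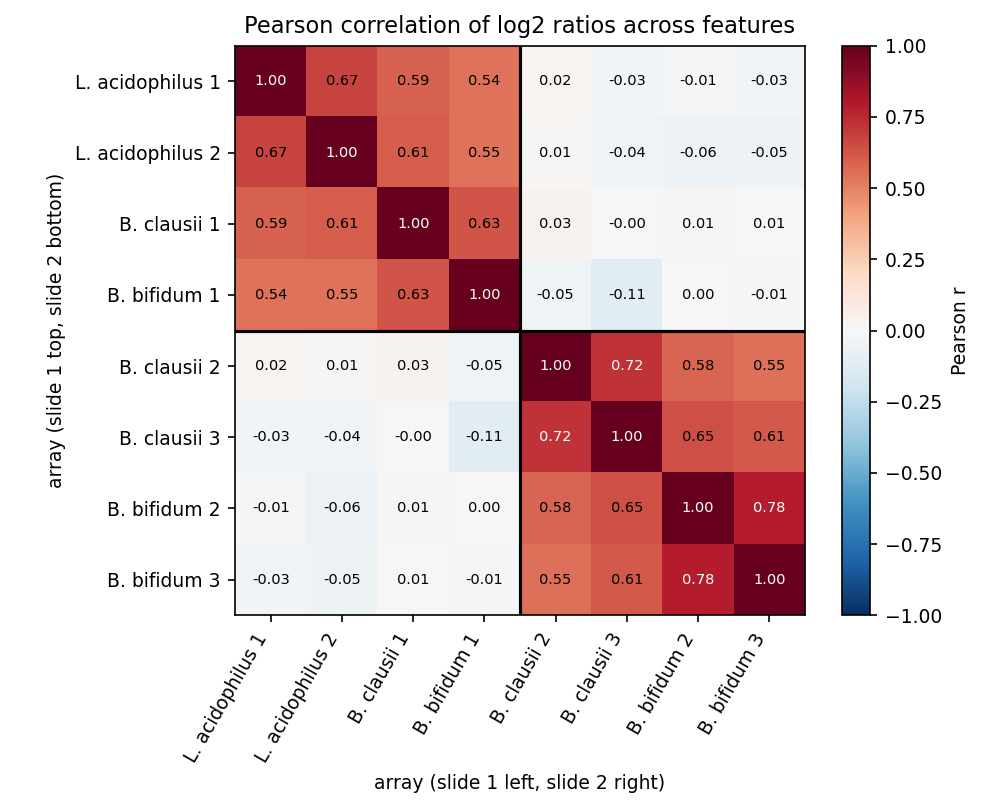
Pearson correlation (colour and number) of log2 ratios across features between each pair of the 8 arrays, with slide 1 above and left of the lines and slide 2 below and right. Arrays of different bacteria on the same slide correlate at 0.544 to 0.646, and arrays of different slides at -0.106 to 0.0335.

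B. clausii against untreated cells. With slide as a block, EGR1, an immediate-early transcription factor, was called higher, by 1.1 ± 0.27 (moderated SE without a block, n = 2), with 0.49 on slide 1 and 1.72 on slide 2. HK2, which encodes a hexokinase of glycolysis, rose by 0.86 ± 0.33, with 0.43 and 1.29. DDIT4, a stress-induced inhibitor of mTORC1 signalling, rose by 0.84 ± 0.31, with 0.18 and 1.49, and ADM, which encodes adrenomedullin, by 0.80, with 0.33 and 1.27. CAPZA1 (0.85, with 0.71 and 0.98), WTAP (0.81, with 0.62 and 1.01), A2ML1 (0.78, with 0.42 and 1.14) and CTNNB1, which encodes beta-catenin (0.77, with 0.82 and 0.72), also rose. WTAP was at least 0.332 higher in all 5 samples, whatever the bacterium, and a dye bias was not tested. The largest falls were in HIRA, a histone chaperone (-0.82, with -0.063 and -1.58), the histone gene H2AC14 (-0.78, with -0.99 and -0.58), PPIL1 (-0.73, with -0.37 and -1.10) and C1orf162 (-0.73, with -0.17 and -1.29). ZNF414 (-0.71, with -0.15 and -1.26), PDPK1 (-0.69, with -0.64 and -0.74), ALG3 (-0.68, with -0.23 and -1.14) and the linker histone gene H1-3 (-0.67, with -0.49 and -0.85) also fell. Blocked adjusted p was 0.00098 for EGR1, 0.000772 for HK2 and 0.00151 for DDIT4.

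The blocked limma fit called 2247 features with B. clausii, 1118 higher and 1129 lower, of which 1506 were named genes. Without a block limma called 0, with 1481 at an unadjusted p under 0.05 and a smallest adjusted p of 0.772, and the blocked error leaves out the difference between the slides. The blocked calls fell to 0 with a normexp offset of 10, with Agilent's LogRatio, with the deposited value table, and without B. clausii replicate 3.

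In the gene lists fixed beforehand, B. clausii was tested in 43 lists and 6 passed camera with the preset correlation. Lists lower than other genes were G2/M and mitosis (median -0.24, adjusted p 5.18e-05), metallothioneins and zinc transport (-0.27, 0.00266) and antimicrobial proteins and NADPH oxidase (-0.15, 0.00284). Higher lists were ATF4 targets of the amino acid response (0.17, 0.00594), glycolysis and hypoxia response (0.13, 0.0167) and cytosolic ribosomal proteins (0.051, 0.0167). None passed with an estimated correlation, where the adjusted p was 0.828 for each of the 6. Under median centring in place of loess the ribosomal median was -0.031, and under Agilent's LogRatio -0.02, while the other 5 kept their sign under each scaling tried. Of these, ATF4 targets came down to 0.0088 and glycolysis and hypoxia to 0.015 under median centring, where the median of all features was -0.031.

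Of 29 G2/M genes, 9 fell and 0 rose with slide as a block, among them the spindle checkpoint gene BUB1B (-0.30 on slide 1 and -0.71 on slide 2) and the kinesin gene KIF11 (-0.43 and -0.57). The list median was -0.0045 on slide 1 and -0.42 on slide 2. The medians on slides 1 and 2 were -0.44 and -0.18 for metallothioneins, -0.099 and -0.19 for antimicrobial proteins, 0.043 and 0.24 for ATF4 targets, 0.061 and 0.13 for glycolysis and hypoxia, and 0.016 and 0.14 for ribosomal proteins. Of 15 metallothionein and zinc genes, 6 fell and 0 rose, with MT1G, a metal-binding protein gene, at -0.67 and -0.38 and MT2A at -0.55 and -0.34. Among 25 antimicrobial genes, 7 fell and 1 rose. The protease inhibitor gene SLPI was at -0.43 and -0.62, the lysozyme gene LYZ at -0.20 and -0.50, S100A8 at -0.022 and -1.01, and NCF4, an NADPH oxidase subunit gene, rose with 0.51 and 0.19. In the glycolysis and hypoxia list, 6 of 38 rose and 1, PFKL, fell (-0.21 and -0.64). Of 24 ATF4 targets, 4 rose, among them SLC7A5, an amino acid transporter gene (0.20 and 0.75), and 1, ALDH1L2, fell. Of 49 ribosomal protein genes, 14 rose and 2 fell. Adjusted over the list alone, the calls numbered 14 for G2/M, 8 for metallothioneins, 11 for antimicrobial, 7 for glycolysis and hypoxia, 7 for ATF4 targets and 20 for ribosomal proteins. Over all features the block called 2247 of 25288. Among features well above background and unsaturated in both channels on all B. clausii arrays it called 1593 of 12552. The member counts were not tested against these shares.

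B. bifidum against untreated cells. With slide as a block, WTAP rose by 0.85 ± 0.16 (moderated SE without a block, n = 2), with 0.65 on slide 1 and 1.06 on slide 2, and ALYREF, an mRNA export factor gene, by 0.83 ± 0.16, with 0.98 and 0.68. ING3 (0.82, with 0.56 and 1.08), CTNNB1 (0.79, with 0.97 and 0.61), MR1, an antigen-presenting molecule gene (0.77, with 0.32 and 1.22), and CAPZA1 (0.76, with 0.71 and 0.81) also rose. WTAP, ALYREF and ING3 were at least 0.332, 0.394 and 0.407 higher in all 5 samples, so their rises are not particular to B. bifidum. A dye bias of these genes was not tested. PPP3R1 (1.12 ± 0.46) and CYP1B1 (0.78) were called higher as well, but at 0.016 and 0.072 on slide 1 against 2.23 and 1.49 on slide 2. The largest falls were SACM1L (-1.07, with -0.057 and -2.08), HIRA (-0.98, with -0.15 and -1.81), CCDC50 (-0.90, with -0.24 and -1.56) and NECTIN2 (-0.88, with -0.22 and -1.54). REEP2 (-0.81, with -0.40 and -1.22), ZNF426 (-0.81, with -0.29 and -1.34), ALG3 (-0.81, with -0.28 and -1.34) and RPS28 (-0.81, with -1.37 and -0.25) also fell. Without B. bifidum replicate 3 another probe stood for RPS28, at 0.321, so the sign of RPS28 depends on the probe. Blocked adjusted p was 0.000266 for WTAP and 0.000381 for ALYREF.

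The blocked fit called 2003 features with B. bifidum, 733 higher and 1270 lower, of which 1323 were named genes. Without a block limma called 0, with 1301 at an unadjusted p under 0.05 and a smallest adjusted p of 0.905, and here too the blocked error leaves out the difference between the slides. These blocked calls also fell to 0 with an offset of 10, with LogRatio and with the deposited value table, and to 38 without B. clausii replicate 3.

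With B. bifidum, 3 fixed lists were lower than other genes under the preset correlation. They were metallothioneins and zinc transport (median -0.27, adjusted p 0.00191), antimicrobial proteins and NADPH oxidase (-0.17, 0.00191) and cholesterol synthesis and SREBP2 targets (-0.13, 0.0125). With an estimated correlation the adjusted p was 0.847 for each. Of 15 metallothionein and zinc genes 4 fell with slide as a block, with MT2A at -0.62 on slide 1 and -0.34 on slide 2, although the list median was -0.50 on slide 1 and -0.0044 on slide 2. Of 25 antimicrobial genes 4 fell (list median -0.12 on slide 1 and -0.18 on slide 2), including the cathelicidin gene CAMP (-0.38 and -0.36). Of 24 cholesterol genes 5 fell (list median -0.15 and -0.12), including MVK, which encodes mevalonate kinase (-0.32 and -0.85), and LSS (-0.19 and -0.84), and 1 rose, HMGCS1 (0.10 and 0.55). The cholesterol median turned to 0.026 under median centring, and there the metallothionein median shrank to -0.069 and the antimicrobial median to -0.025, with all features at 0.018. Adjusted over the list alone the calls numbered 8, 6 and 8. Over all features the block called 2003 of 25288. Among features well above background and unsaturated in both channels on all B. bifidum arrays it called 1571 of 14004. The member counts were not tested against these shares.

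**Figure D2:**
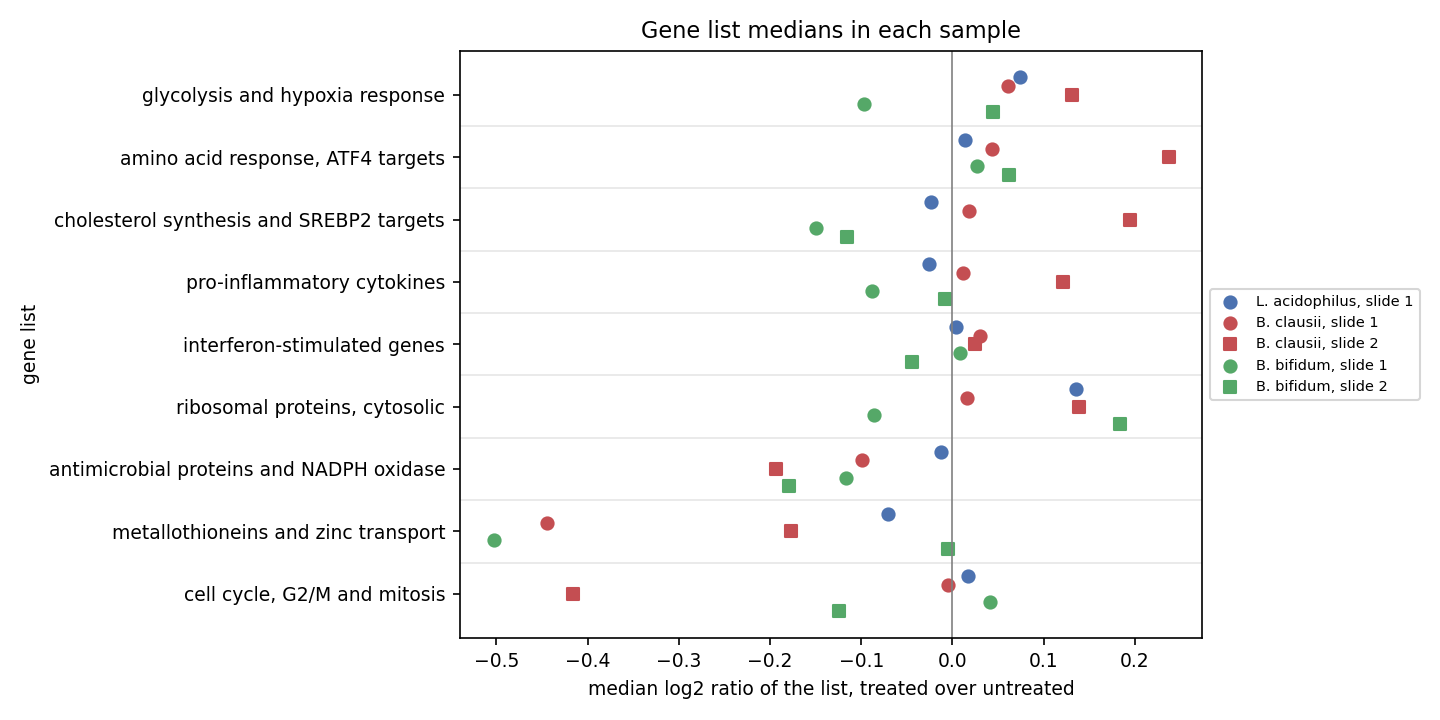
Median log2 ratio of treated over untreated cells for 9 fixed gene lists (rows) in each of the 5 samples, with colour for the bacterium and circles for slide 1 and squares for slide 2. The G2/M median is -0.416 for B. clausii on slide 2 and -0.00445 on slide 1, and the metallothionein median is -0.444 and -0.503 for B. clausii and B. bifidum on slide 1.

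L. acidophilus against untreated cells. No single gene passed the test with this bacterium, which has 1 sample, on slide 1. CXCL10, an interferon-induced chemokine gene, was at 0.54, NFKBIA, a feedback inhibitor of NF-kB, at 0.28, and IL1B at -0.18, none past the test. Cytosolic ribosomal proteins were higher than other genes (median 0.14, adjusted p 0.0299), with 34 of 49 members above 0, though the adjusted p was 0.913 with an estimated correlation. This list call was also lost with an offset of 10, LogRatio, the mean over probes, and without L. acidophilus replicate 1 or 2. The limma count was 0 without a block, with 79 features at an unadjusted p under 0.05, and 0 with slide as a block, with 1661. Median centring moved the median of all features from 0.007 to 0.172 here, and the ribosomal median to 0.91.

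B. clausii against B. bifidum. With slide as a block, 172 features were higher with B. clausii and 0 lower, 79 of them named genes. On slide 1 the difference rests on 1 B. bifidum array, which the comparison with L. acidophilus also uses. Among 9461 named genes well above background in both channels on all arrays, 51 were past 0.5 higher on slide 1 and 2 lower. On slide 2 the numbers were 156 and 118. Low values on that 1 array were not separated from a higher response to B. clausii. ADM had the largest difference, 1.06 ± 0.13 (moderated SE, n = 2 per group, adjusted p 0.00253), with 0.92 on slide 1 and 1.20 on slide 2. NFATC4, a transcription factor gene (1.02, with 1.32 and 0.72), GRK1 (0.98, with 1.25 and 0.72), ARHGEF28 (0.95, with 1.32 and 0.58) and KRT80, a keratin gene (0.92, with 1.04 and 0.80), were also higher. The sizes depended on the processing, and over the settings tried GRK1 ranged from 0.895 to 2.44 and ARHGEF28 from 0.433 to 2.1. List members that were higher were the interferon-induced GTPase gene GBP1 (1.01, with 1.09 and 0.92), DDIT4 (0.90, with 0.56 and 1.24), TNFRSF1B, a TNF receptor gene (0.86, with 1.09 and 0.63) and ALOX12 (0.85, with 1.29 and 0.41). So were STC2 (0.80, with 0.41 and 1.20), NR4A2 (0.76, with 0.94 and 0.58) and SPP1, which encodes osteopontin (0.65, with 0.58 and 0.72). GBP1 was at -0.058 with B. clausii and -1.15 with B. bifidum on slide 1, and at 0.84 and -0.083 on slide 2. NR4A2 was well above background in each channel on 1 of 6 arrays, so its value is near the detection limit. GBP1 was not well above background in both channels on all arrays either, and its difference ranged from 0.604 to 2.34 over the settings tried.

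The count without a block was 0 by limma, with 139 features at an unadjusted p under 0.05 and a smallest adjusted p of 1. The blocked 172 fell to 0 with an offset of 10, LogRatio, the deposited value table or without B. clausii replicate 3, and 35 of the 172 were well above background in both channels on all 6 arrays.

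Of 43 lists, 9 differed under the preset correlation, and the strongest were cholesterol synthesis and SREBP2 targets (median difference 0.19, adjusted p 1.84e-07) and glycolysis and hypoxia response (0.16, 8.6e-07), both higher with B. clausii. On slides 1 and 2 the medians were 0.12 and 0.24 for cholesterol and 0.079 and 0.21 for glycolysis and hypoxia. Interferon-stimulated genes (0.071, adjusted p 0.00736), pro-inflammatory cytokines (0.078, 0.0132) and ribosomal proteins (0.057, 0.0416) were also higher. Their medians on slides 1 and 2 were 0.038 and 0.076, 0.073 and 0.14, and 0.082 and 0.077. The last 4 lists passed on the mean over the slides but had a median near 0 or of the other sign on slide 1. They were immediate-early genes (0.08, adjusted p 0.00831, with 0.0074 and 0.11), anti-inflammatory mediators (0.10, 0.0303, with -0.016 and 0.14), ATF4 targets (0.059, 0.0303, with 0.0034 and 0.17) and G2/M genes (-0.14, 0.000189, with 0.011 and -0.28). With an estimated correlation the adjusted p was 0.69 or 0.799 for every one of these lists. Under median centring the median of all features moved from -0.0063 to -0.1 and that of housekeeping genes from -0.0067 to -0.286, and the medians of all 9 lists except G2/M turned below 0. Cholesterol (-0.082), glycolysis and hypoxia (-0.087), immediate-early (-0.081), anti-inflammatory (-0.063) and pro-inflammatory genes (-0.00052) stayed above all features, while interferon-stimulated genes (-0.14), ATF4 targets (-0.19) and ribosomal proteins (-0.27) did not.

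Chosen after seeing the data, 51 of 9461 bright named genes were at least 0.3 higher with B. clausii than with B. bifidum on both slides, against 9.47 expected if the slides were independent, and 6 were lower, against 6.58. Of the 51, 5 genes, ADM, DDIT4, PFKFB4, SLC16A3 and SLC2A1, were in the glycolysis and hypoxia list, against 0.183 expected (Fisher's exact test, two-sided, adjusted p over 43 lists 3.96e-05). This test treats genes as independent, on the data in which the list had already been seen to differ, with a single sample of each bacterium per slide. By camera with an estimated correlation the list's adjusted p was 0.69. Over the 9461 genes the difference correlated at 0.0647 between the slides. PFKFB4 encodes an enzyme that controls glycolysis, SLC16A3 exports lactate and SLC2A1 takes up glucose. At 0.5, the numbers were 14 higher against 0.841 expected, and 0 lower. Under median centring, whose shift of the median of all features to -0.1 lowers the number past a fixed limit, the 51 became 18.

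**Figure D3:**
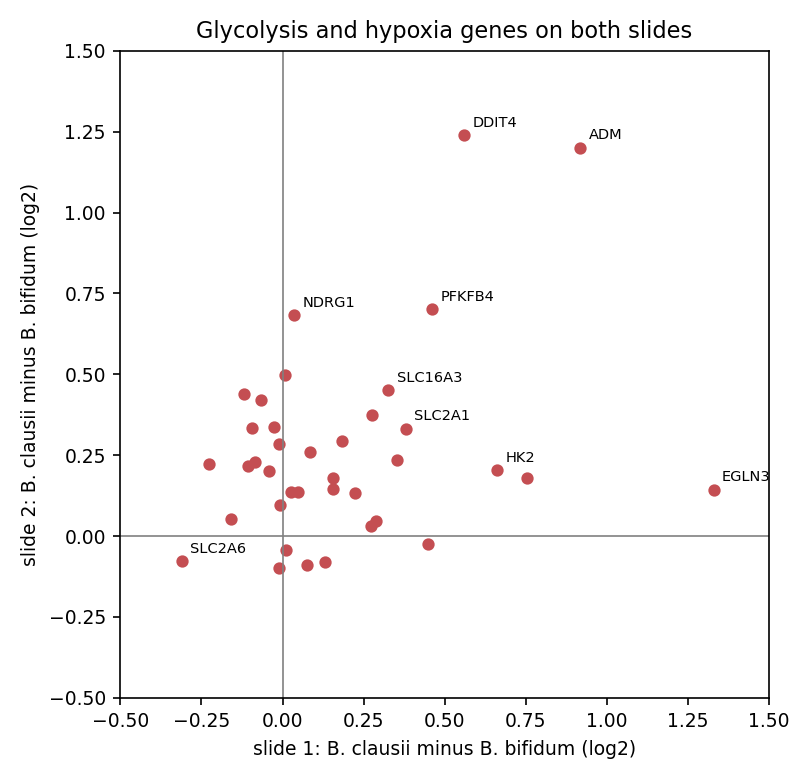
Difference between B. clausii and B. bifidum in log2 ratio on slide 1 (horizontal) and slide 2 (vertical) for each measured gene of the glycolysis and hypoxia list. Of the 34 bright members, 18 are above 0 on both slides, 22 on slide 1 and 28 on slide 2, and independent slides would give 18.1 on both.

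L. acidophilus against the other bacteria. In the fit with slide as a block, 84 features were called against B. bifidum, 82 higher and 2 lower with L. acidophilus, 34 of them named genes. L. acidophilus has 1 sample, so this rests on the assumption that it varies like the other groups. On slide 1 it also rests on 1 B. bifidum array, which the comparison of B. clausii with B. bifidum uses too. LCE5A (1.1), ARHGEF28 (1.09), KRT80 (1.09), RPL37A (0.98) and RPS28 (0.90) were called higher, with differences of 0.98, 1.28, 1.15, 1.07 and 0.86 on slide 1. The sign of RPS28 against untreated cells depended on which of its probes stood for it. The keratinocyte gene LCE5A was at -0.57 with L. acidophilus and -1.55 with B. bifidum on slide 1. No gene list passed camera in this comparison without a block, while some did with it. On slide 1 the list medians ranged from -0.076 for G1/S and DNA replication to 0.23 for metallothioneins and zinc transport. The 84 fell to 0 with an offset of 10, LogRatio, the deposited value table, the mean over probes or without B. clausii replicate 3, and 17 of them were bright. Without a block limma called 0, with 45 features at an unadjusted p under 0.05.

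Against B. clausii the count was 0 without a block, with 29 at an unadjusted p under 0.05, and 0 with it, with 376 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0846. Without a block, G2/M genes were higher with L. acidophilus than with B. clausii (median difference 0.23, adjusted p 1.08e-05), while cholesterol genes (-0.10, 0.0487) and ATF4 targets (-0.18, 0.029) were lower. This contrast sets L. acidophilus on slide 1 against the mean of B. clausii over both slides. On slide 1, which held both bacteria, the median differences were 0.043, -0.039 and -0.018. Other lists lay further from 0 there, such as metallothioneins and zinc transport (0.19) and LXR and PPARG targets (-0.071). With slide as a block more lists passed camera than without it, so the lists named depend on how the slide is treated. With an estimated correlation the adjusted p was 0.902 for each, and under median centring the cholesterol and ATF4 medians turned to 0.51 and 0.47, with a median of all features of 0.175.

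Inflammatory genes fixed beforehand. Of the 15, CXCL10 rose with B. clausii, by 0.48 ± 0.21 (moderated SE without a block, n = 2, blocked adjusted p 0.0296), with 0.48 on slide 1 and 0.49 on slide 2. NFKBIA rose with B. clausii (0.37, adjusted p 0.0282, with 0.30 and 0.44) and with B. bifidum (0.33, adjusted p 0.0482, with 0.46 and 0.20). IL1B fell with B. bifidum (-0.42, 0.0181), with -0.51 and -0.33, and was at -0.26 and 0.34 with B. clausii. The difference between these bacteria in IL1B did not pass (adjusted p 0.302). TNF was at -0.40 and 1.30 with B. clausii, and did not pass (adjusted p 0.1). IL6, IL10, IL12B, CCL20, IFNB1, PTGS2, TNFAIP3, SOD2, IL1RN and TLR2 did not pass with any bacterium in the blocked fit as reported, and the NF-kB target, chemokine and inflammasome lists passed no list test. IL6, IL10, IL12B, CCL20 and IFNB1 were not well above background in both channels on all arrays. For these genes the lack of a call does not show a lack of response. Under alternatives, TLR2 with B. clausii passed in 7 of 17 settings (lower, smallest adjusted p 0.00124), TNFAIP3 with B. bifidum in 6 (higher, 0.00512) and SOD2 with B. clausii in 3 (higher, 0.00892). In 1 to 3 settings TNFAIP3, IL1RN and TNF were also called with B. clausii, and TLR2, SOD2 and CXCL10 with B. bifidum. The difference between these bacteria in CXCL10 was called in none. The 4 lists of markers of other cell types also passed none. These single-gene calls come from the blocked fit, which made 0 calls with an offset of 10, LogRatio or the deposited value table.

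Responses to the bacteria were compared across features with Pearson's r. It was 0.336 for L. acidophilus and B. clausii, 0.381 for L. acidophilus and B. bifidum, and 0.599 for B. clausii and B. bifidum. A shared untreated reference gave 0.353, 0.354 and 0.5 in simulated data, values set by the equal noise assumed for treated and untreated RNA. They are therefore no test of a shared reference. The r values do not rank the pairs, since L. acidophilus was on slide 1 alone and the others are means over both slides: within slide 1 they were 0.657, 0.596 and 0.627. For B. clausii and B. bifidum r ranged over settings from 0.275 with LogRatio, 0.31 with median centring and 0.452 with an offset of 10 to 0.61 with between-array scaling and 0.792 over features bright on all arrays. Without the only slide 1 array of B. clausii or of B. bifidum, r sets slide 1 against slide 2. It then fell to -0.00576 for L. acidophilus and B. clausii and -0.0435 for L. acidophilus and B. bifidum. Median centring also turned the former below 0. With the untreated channels split between groups the correlations were -0.592, -0.547 and -0.127 over both slides, -0.129, 0.0487 and -0.149 within slide 1, and 0.00736 for B. clausii and B. bifidum within slide 2. An effect shared by both channels of an array enters the split ratios with opposite sign and lowers these values. They therefore cannot show that the likeness is lost without a shared reference. In blocked calls, B. clausii and B. bifidum shared 367 rises and 622 falls, but they also shared slides, and no test separates this from a shared response.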

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

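The tests of a constant dye bias, of dim spots and of the untreated channel in the 172 features below, and of dim spots and a shift at like intensity in the glycolysis and hypoxia genes were chosen after the result was seen. The tests on 572 and 145 features, and of choices of sign and splits, were run on the fit with each array counted as a replicate.

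The log2 ratio of 4611 features differed between the slides (1925 higher and 2686 lower on slide 2), which was a difference between groups of samples that the bacterium does not define. Arrays of different slides had a median correlation of -0.011. A gene-specific dye bias that is the same on every array cannot produce a difference between slides, so this value was no separate test of it. In 11935 features bright on all arrays, arrays of different bacteria on the same slide had a median correlation of 0.752 (0.729 to 0.835), which excludes noise of dim spots. Untreated RNA that differed between the slides cannot be told apart from a change in the treated RNA, since the untreated channel carried 24.6% of the variance of the difference and the treated channel 75.4%. The share of Cy5 spots well above background also split by slide, at 75.2% to 77.9% on slide 1 and 41.6% to 60.5% on slide 2. A technical difference between the slides was not tested as a cause. No biological explanation was tested, since culture and hybridization days are not in the labels.

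With slide as a block, 172 features differed between B. clausii and B. bifidum, all higher with B. clausii. Of these, 79.7% were not well above background in both channels on all 6 arrays, against 52.7% of all features, so noise of dim spots may account for many of the calls, and 35 features were bright. The untreated channel carried a median of 45.5% of the difference, which leaves open an untreated RNA that differed between the arrays. A difference in the response to B. clausii and to B. bifidum stays open for the bright features.

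The median of the glycolysis and hypoxia list was higher with B. clausii than with B. bifidum on both slides, a pattern picked after looking at all 43 lists and 6 comparisons, whose adjusted p was 0.69 with an estimated correlation; 18 of 34 bright members were higher on both slides, against 18.1 expected from the 22 and 28 on each. The median over bright members was 0.0794 on slide 1, which argues against noise of dim spots, and the untreated channel carried 16.3% of the mean difference, which argues against untreated RNA. On each slide the list's median was at a percentile of 99.9 or more among random lists of like intensity. Loess had already removed shifts that follow intensity, so this could not exclude a shift of all genes of like intensity. Nor does it exclude chance in the choice of the list. Other lists were as high, with cholesterol synthesis and SREBP2 targets at 100 on both slides and ribosomal proteins at 100 and 99.3. The loess normalization stays open for the sign: with median centring the medians turned to -0.0857 and -0.147, and the percentile of 100 among matched lists (-0.223 and -0.309) excludes nothing, although a value over 99 had been set to count against loess, because matching on intensity redoes what loess does. A difference in the response to the bacteria also stays open, but not one specific to B. clausii on slide 1, where the median was 0.0744 with L. acidophilus, 0.0609 with B. clausii and -0.0968 with B. bifidum.

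Between L. acidophilus and B. bifidum, 84 features were called with slide as a block, 82 of them higher with L. acidophilus, whose 1 sample is assumed to vary like the other groups. On slide 1 B. bifidum has 1 array, which also enters the comparison with B. clausii, so these 2 comparisons are not independent.

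The next counts set single samples against the noise between arrays of a sample, so they do not show a difference between bacteria. On slide 2 with each array counted, 572 features differed between B. clausii and B. bifidum. The untreated channel carried a median of 0.0999% of that difference, 22.4% were dim against 50.9% of all features, and 61.9% had the same sign on slide 1, against 50.7% of all. On slide 1, 145 differed between L. acidophilus and B. bifidum. Of these, 21.4% were dim in the treated channel of the B. bifidum array, against 7.98% of all features. The difference between B. clausii and B. bifidum had the same sign on both slides in 73.8% of them, against 50.7% of all features. On slide 1 that difference uses the B. bifidum array on which the 145 were called.

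With each array counted as a replicate, the real choice of signs gave 527 genes with B. clausii and 463 with B. bifidum, and 1 of the 4 choices of sign gave as many, with a highest other of 0 in both cases. Comparing B. clausii with B. bifidum, the real split gave 0 and 10 of 10 splits gave as many, with a highest other of 0. These choices and splits are too few for a share under 0.05.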

How the results depend on the processing

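The alternatives counting each array and the replicate block were chosen after seeing the data; the cause was not tested where not named. Without a block, all counts were 0 in every scaling, filter, probe, trend and fold setting, except 2 for B. clausii with only its own samples. Counting each array gave B. clausii 527 and B. bifidum 463, and with the replicate block 3147 and 1811, though replicate numbers do not pair arrays: 3 of 7 same-numbered pairs exceeded a correlation of 0.1 (-0.0549 to 0.69), and 5 of the 7 share a slide. Counts within a slide set single samples against technical noise. Within slide 1, counting each array gave L. acidophilus 661, B. clausii 308, B. bifidum 1678, L. acidophilus against B. bifidum 145 and B. clausii against B. bifidum 1. Within slide 2 they were B. clausii 9962, B. bifidum 7335 and their difference 572. The slide block gave 2247, 2003, 84 and 172, and 3 lists for L. acidophilus.

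With the block, counts for B. clausii, B. bifidum, L. acidophilus against B. bifidum and B. clausii against B. bifidum were 0 with offset 10, with Agilent LogRatio and with the deposited value table. Median centring gave L. acidophilus 1, B. clausii 4509, B. bifidum 5472, L. acidophilus against B. clausii 5 and B. clausii against B. bifidum 1317. Scale gave 7 for L. acidophilus and 7 against B. clausii. L. acidophilus against B. bifidum was 40 with no filter and 5 with the strict filter, which gave 9 for B. clausii against B. bifidum. The mean over probes gave 1063, 928, 0 and 95. The trend gave L. acidophilus 70, B. clausii 3510, B. bifidum 3192, L. acidophilus against B. clausii 7 and against B. bifidum 185. At 2-fold the counts were 5, 14 and 27 for B. clausii, B. bifidum and their difference. Counting each array gave L. acidophilus 175, B. clausii 5171, B. bifidum 4160, L. acidophilus against B. bifidum 35 and B. clausii against B. bifidum 86.

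Without a block, lists numbered 0 for every bacterium with an estimated correlation or fry; with the block fry called 1 list for L. acidophilus and 1 for B. bifidum, and an estimated correlation 0. For L. acidophilus they were 0 with offset 10, LogRatio and the mean over probes, and 22 with median centring, for B. clausii 3 with LogRatio, and for B. bifidum 5 with median centring. With split controls, where effects shared by both channels of an array lower the values, correlations were -0.592, -0.547 and -0.127 over both slides, but -0.129, 0.0487 and -0.149 within slide 1 and 0.00736 within slide 2. L. acidophilus and B. clausii came to -0.245 with median centring, under which the hypoxia medians were -0.0857 and -0.147 and the 51 genes became 18.

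Leaving out each array in turn gave, without a block, 0 to 11 for B. clausii and 0 to 14 for B. bifidum (the highest without B. bifidum replicate 1), 0 to 2 for L. acidophilus against B. bifidum and 0 to 1 for B. clausii against B. bifidum. With the block it gave 0 to 4 for L. acidophilus, 0 to 2344, 38 to 2647, 0 to 3 for L. acidophilus against B. clausii, 0 to 219 and 0 to 274, with the lowest for B. clausii, B. bifidum and both differences from B. bifidum without B. clausii replicate 3. Lists ranged from 0 to 1, 5 to 6 and 1 to 4. Correlations ranged from -0.00576 to 0.339, -0.0435 to 0.384 and 0.438 to 0.603, and the 51 genes from 47 to 55. The correlations below 0 came without replicate 1 of B. clausii or of B. bifidum, which sets slide 1 against slide 2. Without B. clausii or B. bifidum replicate 1 the block left no residual degrees of freedom and gave no value, as did only own samples for L. acidophilus. Hypoxia medians ranged from 0.211 to 0.234 on slide 2; on slide 1 (0.0794) neither array entering it could be left out.

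Of 325 named gene values, offset 10, LogRatio and the value table each left 245 below the threshold, and leaving out B. clausii replicate 3 left 228 of 322. Reversed values were RXRA 0.0194 and YWHAZ -0.0652 with B. clausii and YWHAZ -0.0778 with B. bifidum (mean over probes). RPS28 was also reversed, and over left-out arrays it ranged from -0.567 to 0.456 with B. clausii and from -0.821 to 0.321 with B. bifidum. It turned without B. bifidum replicate 3. Leaving out that array does not change the B. clausii samples, so another probe of RPS28, of the other sign, then stood for the gene. The sign of RPS28 therefore depends on the probe. Opposite calls by probes of a gene occurred in 28 of 2034 genes with B. clausii and 18 of 1654 with B. bifidum. A median signal over background as low as 2.33 limits the ratios of dim probes.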

Other observations

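The counts in this part were chosen after seeing the data.

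In all 5 samples, 16 bright named genes were at least 0.3 higher and 11 at least 0.3 lower than in untreated cells. The higher genes included the translation factor gene EEF1A1 (0.611 to 0.962), the mRNA export gene ALYREF, and the ribosomal protein genes RPL35, RPL14, RPL41, RPL7A and RPS2. The lower genes included CDK1, the kinase that drives entry into mitosis (-0.329 with L. acidophilus, -0.374 and -0.393 with B. clausii, -0.588 and -0.369 with B. bifidum), RPA3, a DNA replication protein gene, and RPL39. A dye bias of these genes was not tested, since no array has swapped dyes.

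Of the NF-kB pathway genes, NFKBIE and BCL3 were called lower with both B. clausii and B. bifidum, while NFKBIA was called higher with both, and the list passed no test. NFKBIE was at -0.102 and -1.15 with B. clausii and 0.0239 and -1.34 with B. bifidum on slides 1 and 2, and BCL3 at -0.00856 and -0.849, and 0.0999 and -1.01. IL18, a cytokine of the inflammasome pathway, had its sign on both slides, at -0.162 and -0.521 with B. clausii and -0.293 and -0.585 with B. bifidum. IRF9, a transcription factor of the interferon response, was at 0.592 and 0.0236 with B. clausii, and at 0.526 and 0.106 with B. bifidum.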
